A study of Mus musculus with 2 samples.

How the data were processed

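The series holds DNase-seq of cerebellum tissue from 2 male B6CASTF1/J F1 mice aged 2 months. The labels number the animals 05 and 06 and call them biological replicates 1 and 2, and they form 1 group of n = 2. For each library there are 2 deposited peak lists, a table of false discovery rates along the genome and a list of footprints. Per the text deposited with each library, all files come from the filtered alignments of that library to mm10, with no pooling of the animals. The aligner, the peak caller and their versions are not given in the sources used here.

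The signal value of each peak, the height used here, was deposited by the authors as a density of DNase I cleavage scaled by the library's depth. The heights are whole multiples of a smallest step (all within a tolerance of 0.1 steps), which was read as 1 cleavage event, so the number of events behind a peak is its height divided by the step. If the values are per 1 M events, the steps imply 271 M and 137 M events in replicates 1 and 2. This reading of the scale was not stated in the labels, while the ratio of the steps, 1.98, needs no such reading. The median peak held 124 events in each library, with a counting error of 8.98%. The false discovery rates (an adjusted p-value) were deposited by the authors only for positions below 0.05. In the footprint lists the deposited p-value column holds the constant 0.01, the authors' threshold, so footprints could not be ranked. The looser peak list was used as the main one. Its peaks reach an FDR of 0.05, and those of the stricter list all hold a position at or below 0.001.

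Files were read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, statistics came from scipy 1.17.1 and plots from matplotlib 3.10.9. The assembly was GRCm38.p6, the same build as mm10, and genes came from the basic annotation of GENCODE M21. No peak ran past a chromosome's end, and 0 and 2 peaks lay over unknown bases. Autosomes and the X and Y chromosomes were used, and other sequences were left out.

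Peaks were counted as shared where they overlapped by at least 1 bp, against 100 placements in which each chromosome's peaks were moved by a random offset. Heights of shared peaks were compared by Pearson and Spearman correlation across peaks, with no p because peaks are not independent replicates. Classes were assigned by the peak's midpoint, in the order promoter (within 1 kb of a start site), exon, intron and intergenic. For the gene lists, the named peaks and the motifs, a peak was a promoter peak where any part of it lay within 1 kb. For each of 22 gene lists of 6 to 16 genes (246 in all), the tallest promoter peak per gene and the peaks in and within 10 kb of the gene were averaged. Each mean was given as a percentile among 10000 random lists of protein-coding genes of the same size, matched on gene length in 10 bins. A list was called high or low where both libraries lay in the outer 2.5% of random lists on the same side.

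The lists cover granule neurons and their progenitors, Purkinje neurons, inhibitory interneurons, astrocytes with Bergmann glia, oligodendrocytes and their precursors, microglia, vascular cells, choroid plexus with ependyma and meningeal fibroblasts. Further lists cover forebrain regulators, Hox genes, liver, skeletal muscle, lymphocytes, erythroid cells, the germline, immediate early genes, the clock, imprinted genes and housekeeping genes. Of the 16 imprinted genes 12 were protein-coding and entered the percentile.

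Footprints were counted as shared at 50% reciprocal overlap, against 20 random placements. In named peaks, a shared footprint was searched for motifs over the whole stretch that the footprints of both animals span. A match there can thus reach outside the footprint of 1 animal. For 32 consensus motifs, the share of footprints (20 bp added on each side) holding a match on either strand was divided by that of control windows of the same width, placed at random in the same peaks outside footprints with up to 30 tries. Control windows were found for 98.4% and 95.8% of the footprints in peaks. Ratios have 95% intervals on the log scale for counting error only, and a motif was called where both intervals excluded 1 on the same side. A ratio needed at least 5 matches, which HNF1 sites did not reach.

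Named genes followed a rule. In each list these were the 3 members with the highest mean promoter height and up to 2 members with no promoter peak in either animal. Over all genes these were the 10 highest promoters and the 10 highest distal peaks, leaving out the Y chromosome. Some items that the rule or the lists name are not reported here. The central 50 bp of the highest promoter and distal peaks were searched in the genome, and 19 of them had 1 exact copy.

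The tests, lists, motifs, named-gene rule and 26 alternatives were fixed before the data were examined. A further 3 alternatives were chosen after seeing the data: gene lists on the stricter peak list, gene lists matched on GC content of the promoter, and motifs in promoter footprints only. The other alternatives changed the overlap, the peak list, the promoter window, the flank of genes, the matching of lists, the added bases and the control windows, or left out each replicate.

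The steps were tested on simulated data. Of 200 random lists of 12 genes among 21938, 0.5% were called high and 1.5% low by promoter height. With the heights of the listed genes raised 2-fold, 48.5% were called high, and with 4-fold, 93.5%. With 60.0% of peaks left in place, the overlap step found 60.7%. The excess was 1174 moved peaks, and all 1174 overlapped an unmoved neighbour of their own list. Sites of CTCF and of NEUROD1 and ATOH1 were written into 10% of the footprint windows among 50000 simulated windows, and 10.0% and 9.96% were recovered.

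Allele-specific signal was not analysed here, because the files hold no reads. Percentiles describe these libraries, and p-values across genes or peaks were not computed.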

Results

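DNase I accessibility was measured in the cerebellum of 2 male F1 mice (B6CASTF1/J) aged 2 months, 1 library per animal. The animals form 1 group, so the only comparison between samples is between replicate 1 (animal 5) and replicate 2 (animal 6). DNase I cleaves DNA where chromatin is open, and the density of cleavage at a peak is called its height here. Replicate 1 held 181007 peaks and replicate 2 held 141281. Heights moved in steps of 0.00369 in replicate 1 and 0.00731 in replicate 2. A step was read as 1 cleavage event, so replicate 1 was taken as 1.98 times as deep. The median peak held 124 events in each library, which gives a counting error of 8.98%. Values of named items are given for both animals, replicate 1 first, and with n = 2 no test across animals was made. Heights are the authors' own values, each on its library's scale, and coordinates are on mm10.

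Which regulatory regions of the adult cerebellum are open was asked first from the tallest promoters. Dynlt1b, which encodes a dynein light chain, had heights of 58.9 and 93.1 at its start site (chromosome 17, 6430021 to 6430180). Bahcc1, a chromatin reader gene, reached 52.2 and 92.3, and Nup107, which encodes a nuclear pore protein, reached 30.6 and 93.9. A second nuclear pore gene, Nup50, stood at 29.0 and 74.7, and a footprint shared by both animals there held the NRF1 palindrome GCGCATGCGC (chromosome 15, 84923261 to 84923270). Rragc, a GTPase of the amino acid response, stood at 35.8 and 76.99, Rab40c at 42.7 and 66.9, the potassium channel subunit gene Kcnab2 at 39.9 and 65.3, and the inositol phosphate kinase gene Ipmk at 29.9 and 74.6. Some of these peaks were also the tallest promoter peak of other genes. The Kcnab2 peak was shared with Nphp4, the Rab40c peak with Gm16278, and the Rragc peak with Gm12905 and 4930535I16Rik. Shared footprints at Dynlt1b and Nup107 held the SP and KLF box GGGGCGGGG. The pseudogene 2610005L07Rik had heights of 23.2 and 80.4, and the noncoding gene Gm42418 had 58.8 and 51.5. The central 50 bp of the Gm42418 peak occur at 2 places in the genome, so the place of this signal is uncertain.

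Promoters were the tallest class of peaks. Peaks within 1 kb of a start site made up 20.2% and 24.6% of all peaks (22.4% ± 3.10, SD, n = 2), on 4.37% of the known bases, and 55.4% and 66.5% of the tallest 10% of peaks. Their median heights were 0.997 and 2.18, against 0.454 and 0.812 for introns and 0.321 and 0.636 for intergenic peaks. Introns held 45.4% and 42.3% of the peaks, exons 5.93% and 6.18%, and intergenic sequence 28.5% and 26.9%. A promoter peak was found for 14563 and 14565 of 21938 protein-coding genes, and for 14135 of them (64.4%) in both animals.

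Each of the 15 granule neuron genes had a promoter peak in both animals. The tallest were Cbln3, a cerebellin gene of granule cells (28.7 and 32.1), Neurod1, an E-box-binding neuronal regulator (23.8 and 24.3), and Cbln1, which encodes a synapse organiser secreted by granule cells (13.3 and 32.0). Shared footprints in the Cbln1 promoter held CCCCGCCCC at 3 places, the first at chromosome 8, 87472631 to 87472639. The list's mean promoter height lay at percentiles 99.9 and 93.0 of random gene lists of the same length, so it passed the upper limit in replicate 1 but not in replicate 2. By peaks in and within 10 kb of the gene it passed in both, with means of 38.5 and 29.4 peaks per gene and percentiles of 99.9 and 99.9.

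All 10 genes of the granule progenitor list also had promoter peaks in both animals. Cdk1, the mitotic kinase gene, stood at 9.11 and 15.7, with the NFY box CCAATCAG in a shared footprint (chromosome 10, 69352988 to 69352995). Top2a, a topoisomerase of dividing cells, stood at 11.9 and 7.90, and Ptch1, the Hedgehog receptor gene, at 9.19 and 9.53. The list's mean height was not set apart from random lists, at percentiles 26.2 and 13.4.

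Purkinje neuron genes were mixed. Itpr1, the calcium release channel gene of Purkinje cells, had promoter heights of 16.8 and 24.5, Lhx1 of 11.7 and 20.004, and Aldoc, the zebrin antigen gene, of 9.42 and 10.5. Pcp2 and Ppp1r17, both known for expression in Purkinje cells, had no promoter peak in either animal. The list had promoter peaks in both animals at 12 of 15 genes and lay at percentiles 14.2 and 8.17 by promoter height. By peaks in and near the gene it was high, at 97.7 and 98.9, a call that ended with 50 kb around the gene (90.7 and 95.8), with equal numbers of the highest peaks (97.3 and 98.9) and on the stricter peak list (97.2 and 97.9).

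Genes of inhibitory interneurons and glia had low promoters in these libraries of whole tissue. Each height mixes all cells of the tissue, so a low one does not show a promoter closed in the named cells. In the interneuron list, 8 of 13 genes had promoter peaks in both animals, led by Lypd6 (1.92 and 3.90), Nxph1 (1.71 and 3.32) and the vesicular GABA transporter gene Slc32a1 (0.864 and 0.980, in a different peak in each animal), while Tfap2b and the glycine transporter gene Slc6a5 had none. Its percentiles were 0.01 and 0. The astrocyte and Bergmann glia list, at percentiles 0.29 and 0.28, had peaks at 11 of 12 promoters, led by the glutamate transporter gene Slc1a2 (3.79 and 6.52), the lipid carrier gene Fabp7 (2.83 and 7.06) and Hopx (1.12 and 2.87). Of 12 oligodendrocyte genes 8 had them, with the myelin genes Mbp (2.85 and 7.06) and Cnp (1.51 and 4.74) and the myelin regulator Myrf (1.11 and 4.42) ahead and with none at Sox10, and the list lay at 0.18 and 0.34. The precursor list, with C1ql1 (1.04 and 2.36), Ptprz1 (0.883 and 2.41) and the growth factor receptor gene Pdgfra (0.587 and 2.22), lay at 1.16 and 1.15. A shared footprint in Pdgfra held the CTCF site GCCCTCTAGTGG (chromosome 5, 75156372 to 75156383).

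Microglial, vascular, choroid plexus and meningeal genes were low as well. In the microglial list 8 of 12 genes, the receptor genes Cx3cr1 and Csf1r among them, had no promoter peak in either animal, and Sall1 (0.554 and 1.23) had one in both, whereas Tmem119 had one in replicate 2 alone (0.366). Its percentiles were 0.08 and 0.11. The vascular list lay at 0 and 0, with low peaks at the endothelial receptor genes Kdr (0.288 and 1.21) and Flt1 (0.388 and 0.987) and at Kcnj8 (0.332 and 0.804), and none at the junction genes Pecam1 and Cdh5. In the choroid and ependymal list Foxj1, a regulator of cilia, stood at 3.58 and 9.74, Otx2 at 1.63 and 1.56 and Ccdc153 at 0.683 and 2.29, while Folr1 and Kcnj13 had no promoter peak. In the meningeal list the collagen gene Col1a1 stood at 2.68 and 10.3, in a peak 957 bp from its start site with the CTCF site GCCACCTAGTGG, Foxc1 at 0.654 and 0.936 and Foxc2 at 0.643 and 0.5995, and Dcn and Lum had none. The choroid and ependymal list lay at percentiles 1.565 and 1.11 and the meningeal list at 1.13 and 1.60. With a window of 500 bp, Col1a1 and Ccdc153 had no promoter peak.

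Genes of other tissues and brain regions mostly had low promoter peaks or none. The liver list had a promoter peak at 1 of 12 genes, Apob (0.613 and 2.93), and none at Alb or Apoa1, with percentiles of 0 and 0. The Hox list had no gene with a peak in both animals, with a peak at Hoxa4 in replicate 1 alone (0.273), at Hoxb5 in replicate 2 alone (0.468) and at Hoxa2 and Hoxa3 in neither, and percentiles of 0.01 and 0.03. The forebrain list lay at 0.98 and 2.47, with no peak at Fezf2 and low ones at Tbr1 (0.576 and 1.24) and Neurod6 (0.698 and 0.402). The lymphocyte list lay at 0.83 and 0.07, with no peak at Cd3e or Cd3d and 0.1699 in replicate 1 alone at Pax5, yet the recombinase gene Rag1 had heights of 7.45 and 3.58 and an E-box CCATCTGT in a shared footprint (chromosome 2, 101649213 to 101649220). In the erythroid list, at 1.01 and 0.87, Epor stood at 1.40 and 2.65 and Tal1 at 0.395 and 0.512, and the globin genes Hba-a1 and Hbb-bt had none. The germline list lay at 0.51 and 0.54, with Dazl at 8.02 and 16.5, Ddx4 in replicate 2 alone (0.373), Sycp3 in replicate 1 alone (0.192) and no peak at the protamine genes Prm1 and Prm2. Skeletal muscle genes lay at 13.7 and 4.27 and were not called low. Mylpf, a myosin light chain gene, stood at 20.8 and 21.9, in a different peak in each animal, while Tnnt3 stood at 0.868 and 1.499, Des at 0.921 in replicate 2 alone and Myod1 and Myog had no peak.

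Inducible, clock and housekeeping genes had tall promoters. All 12 immediate early genes had promoter peaks in both animals, led by Jun, a subunit of AP-1 (31.7 and 37.2), the phosphatase gene Dusp1 (24.3 and 44.2) and the zinc finger gene Egr1 (17.0 and 43.4). Dusp1 held the cAMP response element TGACGTCA in a shared footprint (chromosome 17, 26508608 to 26508615). All 10 circadian clock genes had them too, led by Tef (25.2 and 57.7), the period gene Per1 (36.8 and 40.1, in a different peak in each animal) and the nuclear receptor gene Nr1d1 (29.9 and 46.5). Both lists lay at percentile 100 in both animals. The housekeeping list, led by Rplp0 (28.7 and 41.3), Ywhaz (24.0 and 30.7) and Ppia (16.8 and 36.0), lay at 99.8 and 99.9. Imprinted genes, with Inpp5f at 17.8 and 26.1, Peg3 at 16.0 and 25.1 and Snrpn at 7.41 and 15.8, lay at 56.8 and 45.8.

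Of the 22 lists, 3 were high and 14 low by promoter height, where a call needed both animals in the outer 2.5% of random lists on 1 side. A percentile describes these libraries and is not a test across animals. Nor does a low call tell cell types of the cerebellum from other tissues. The interneuron list (0.01 and 0) and the lymphocyte list (0.83 and 0.07) were both low. By peaks in and near the gene, 4 lists were high, the granule neuron, Purkinje neuron, immediate early and clock lists, and 3 low, the Hox, vascular and germline lists. Matching random lists on GC content of the promoter, a choice made after the data were seen, ended the calls of the immediate early (62.6 and 69.2), clock (97.46 and 90.5) and vascular (1.91 and 3.01) lists by nearby peaks and of the choroid list by promoter height (2.75 and 2.60), and set skeletal muscle low by promoter height (mean percentile 0.64) and the forebrain list low by nearby peaks (0.125 and 0.42). With no matching, the calls of the immediate early (93.1 and 95.4), clock (99.2 and 97.475), vascular (4.33 and 6.29) and germline (3.78 and 2.10) lists by nearby peaks and of the oligodendrocyte precursor list by promoter height (2.02 and 2.57) ended, and the liver list was low by nearby peaks (0.315 and 2.495). The germline call by nearby peaks also ended with 50 kb around the gene (21.1 and 20.6) and on the stricter list (4.17 and 1.46), and 50 kb set skeletal muscle high (99.2 and 97.6). Among named promoters, a window of 500 bp gave no peak at Apob or Tnnt3 and lower mean heights at Ptch1 (3.36), Lypd6 (0.815), Epor (0.628) and Peg3 (12.9), and the stricter list a lower one at Foxc2 (0.321).

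**Figure D1:**
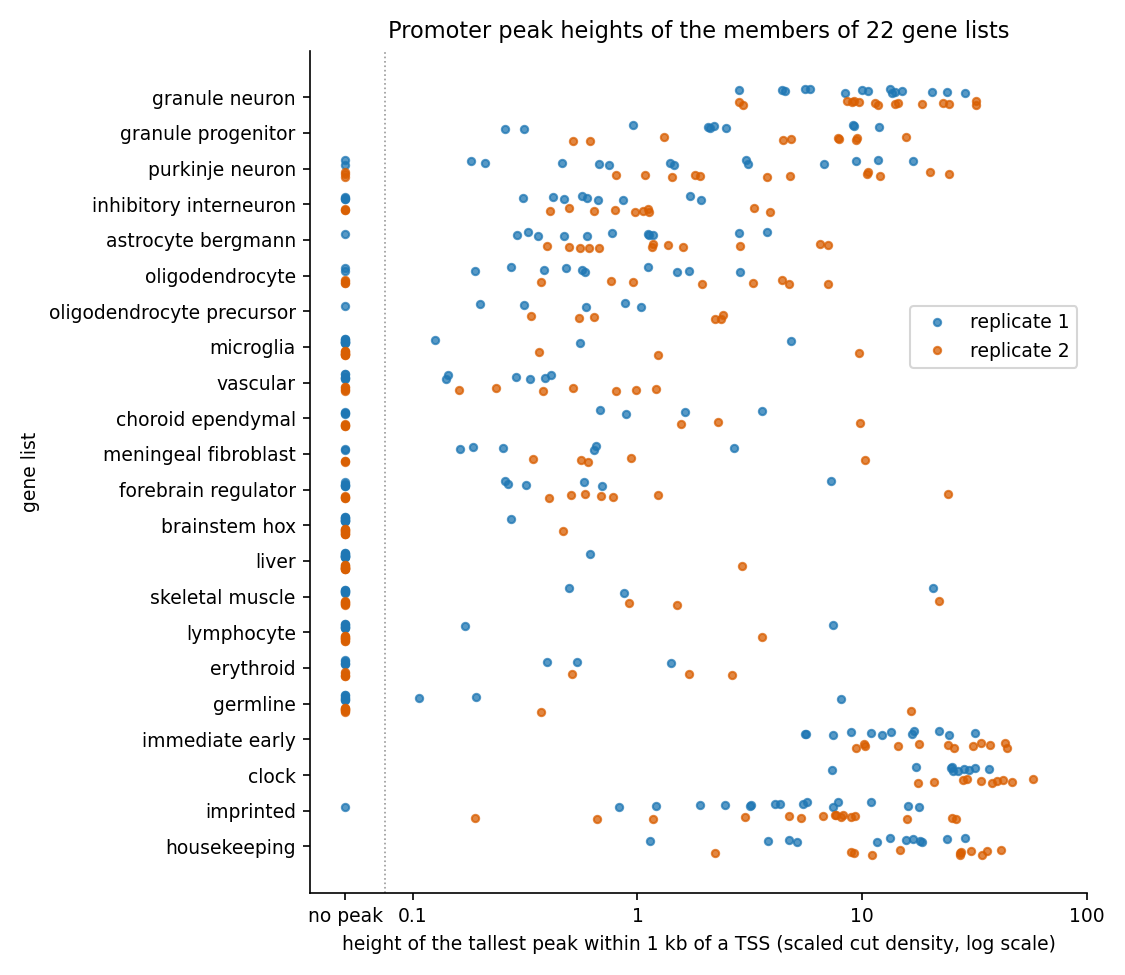
Height of the tallest promoter peak within 1 kb of a start site (log scale, scaled cleavage density) for each member of 22 gene lists, 1 point per gene and animal, with genes lacking a peak at the left. Immediate early, clock and housekeeping genes sit at the right, and liver and Hox genes mostly lack a peak.

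Distal open regions, over 1 kb from any start site, reached the heights of tall promoters. The tallest lay in Vps37c, a gene of endosomal sorting (chromosome 19, 10709501 to 10709660, 32.1 and 77.8), 20816 bp from the nearest start site. Next came a peak 1592 bp from the start site of the noncoding gene Gm10655 and 1765 bp from that of Tle3, a corepressor gene (chromosome 9, 61370441 to 61370760, 38.6 and 53.8), and a peak in Dync1li2 (chromosome 8, 104436141 to 104436340, 23.5 and 60.8), 2019 bp from the start site of Gm45731. A peak in Arhgap26 (chromosome 18, 39039221 to 39039380, 27.7 and 54.1) lay 45109 bp from the start site of Gm15334, and a peak in Smyd3 (chromosome 1, 179012341 to 179012560, 33.9 and 45.7) lay 94837 bp from that of Gm16564. A peak inside both 9330198N18Rik and the noncoding gene Gm14486 (chromosome 2, 30658501 to 30658720, 25.3 and 54.97), 19400 bp from the start site of Gm14486, held the RFX box variants GTTGCCATGG and GTTGCCACGG in shared footprints. The peak in Maml3, a Notch coactivator gene (chromosome 3, 52088441 to 52088640, 27.6 and 51.3), lay 15154 bp from the start site of 5430420F09Rik. A peak in C87436 and in an exon of A430078I02Rik (chromosome 6, 86472221 to 86472520, 28.4 and 48.9), 8459 bp from the start site of A430078I02Rik, held TGACGTCA at 2 places and the EGR box GCGTGGGCG. The others lay in Mamstr (chromosome 7, 45643521 to 45643860, 32.6 and 44.3), 3698 bp from its start site, and 4945 bp from that of Txn2 (chromosome 15, 77933841 to 77934060, 18.7 and 57.1).

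Which factors left marks in open chromatin was asked from the footprints, short stretches protected from cleavage inside open regions. Motifs were matched by consensus sequence, and a match does not show which factor was bound. Sites of CTCF, the insulator protein, were 8.53-fold (95% interval 7.91 to 9.20) and 5.69-fold (5.32 to 6.09) more frequent in footprints than in control windows of the same peaks. NFI sites, known in granule neuron maturation, were 6.04-fold (4.95 to 7.36) and 6.03-fold (4.85 to 7.49) more frequent, and full RFX sites 6.04-fold (3.89 to 9.39) and 3.52-fold (2.29 to 5.39). The E-box of NEUROD1 and ATOH1, regulators of the granule lineage, lay in 3.24% and 3.11% of footprints, 1.68-fold (1.64 to 1.73) and 1.62-fold (1.56 to 1.68) over control windows, and the ZIC box 1.34-fold (1.31 to 1.37) and 1.38-fold (1.34 to 1.42). Among promoter-type motifs, NRF1 stood at 2.75-fold and 2.38-fold, CREB at 2.09-fold and 1.67-fold and SP and KLF at 1.82-fold and 1.60-fold. The size and order of these ratios depended on the 20 bp added on each side of a footprint. With 0 bp added, CTCF stood at 337-fold and 303-fold, CREB at 37.3 and 27.9, SP and KLF at 22.3 and 12.7, the E-box at 6.25 and 4.84 and the ZIC box at 2.86 and 3.08, while NFI, full RFX and NRF1 sites had too few matches in control windows for a ratio.

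Of 30 motifs with enough matches, 16 were more frequent in footprints in both animals and 4 less frequent. The 16 were not limited to the granule lineage. They included OLIG sites (1.36 and 1.25), EBF sites, listed for Purkinje neurons (1.30 and 1.18), and TFAP2 sites, listed for interneurons (1.23 and 1.17). The less frequent ones were LHX and other homeobox sites (0.870 and 0.737), RORA (0.879 and 0.765), SOX (0.916 and 0.884) and GATA (0.769 and 0.767). With control windows matched on GC content none of the 4 calls held, though GATA stayed at 0.824 and 0.864 and SOX at 0.951 and 0.935, with upper bounds in replicate 2 of 1.005 and 1.0004. MEF2 sites went opposite ways, at 1.23-fold (1.104 to 1.38) in replicate 1 and 0.815-fold (0.689 to 0.964) in replicate 2, but GC-matched control windows gave 1.42-fold (1.26 to 1.597) and 0.941-fold (0.789 to 1.12), and with 0 bp added to the footprints both lay below 1 (0.904, 0.609 to 1.34, and 0.311, 0.171 to 0.567). Intervals cover counting error only, and windows are not independent replicates.

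**Figure D2:**
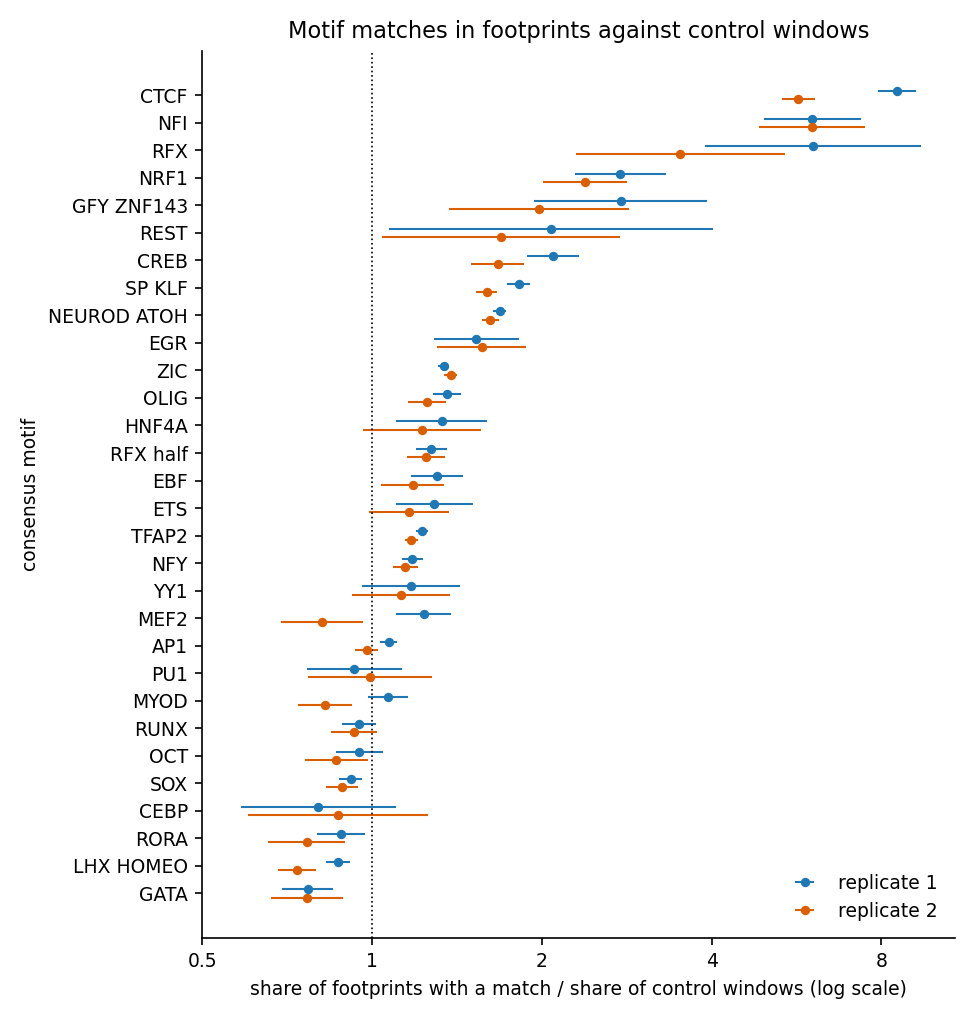
Share of footprints with a motif match divided by the share of control windows in the same peaks (log scale), for 30 motifs in each animal, with 95% counting intervals as bars. CTCF, NFI and RFX sites stand farthest to the right, and MEF2 lies on opposite sides of 1 in the 2 animals.

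Replicate 1 held 526092 footprints of median width 10 bp, and replicate 2 held 324168 of 12 bp. Of these, 80.9% and 85.6% lay in peaks, and 29.5% and 47.9% were found in the other animal at 50% reciprocal overlap, against 0.0937% and 0.154% at random places. Promoter peaks held 12.5 and 12.1 footprints per kb and distal peaks 11.03 and 10.7. At equal numbers of events distal peaks held more in each class below 800 events, such as 13.6 and 14.05 per kb at 200 to 400 events, against 9.39 and 7.46 in promoter peaks.

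The tall regions were shared by both animals and the low ones often were not. Of the tallest 10% of peaks, 99.5% in replicate 1 and 98.8% in replicate 2 had a partner in the other animal, against 13.98% and 38.4% of the lowest 10%. Promoter peaks had a partner in 78.0% and 83.2% of cases and intron peaks in 59.1% and 81.6%. Across all peaks 62.3% and 80.5% were shared, against 2.07% and 2.64% at random places. Across 107646 pairs of shared peaks, which are not independent replicates, Pearson's r of log2 heights was 0.890 and Spearman's rho 0.872.

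**Figure D3:**
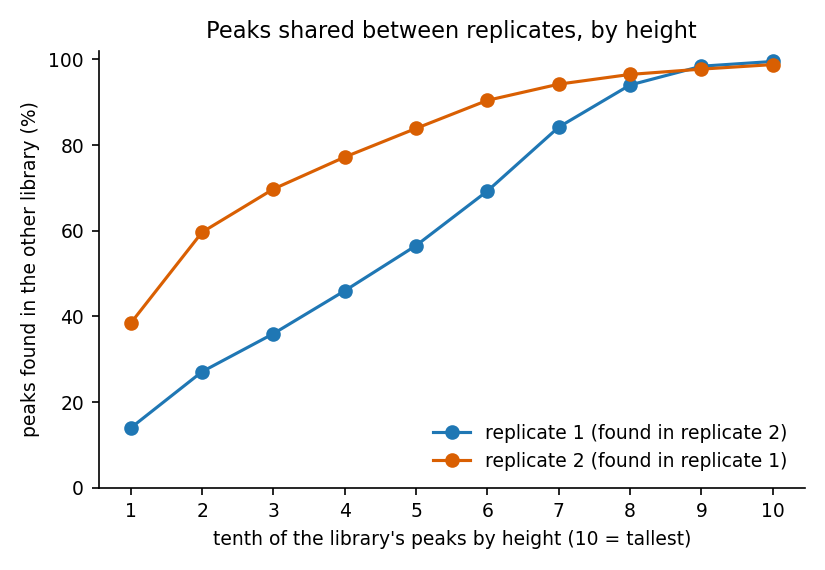
Percent of each animal's peaks with a partner in the other animal, by 10 classes of peak height within the library (10 is the tallest). The share goes from 13.98% to 99.5% in replicate 1 and from 38.4% to 98.8% in replicate 2.

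Heights scaled by depth still differed between the 2 libraries. The shared peaks were taller in replicate 2 in 76.2% of pairs, with a median ratio of 1.48 (quartiles 1.02 and 2.18). The median ratio was 1.81 at promoters, 1.32 in introns and 1.44 in intergenic sequence, and it went from 1.11 at 40 to 45% GC to 2.21 at 65% GC and over. Cbln1 and Egr1 differed by more than this median, while Neurod1 (23.8 and 24.3) and Top2a (11.9 and 7.90) lay below it.

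**Figure D4:**
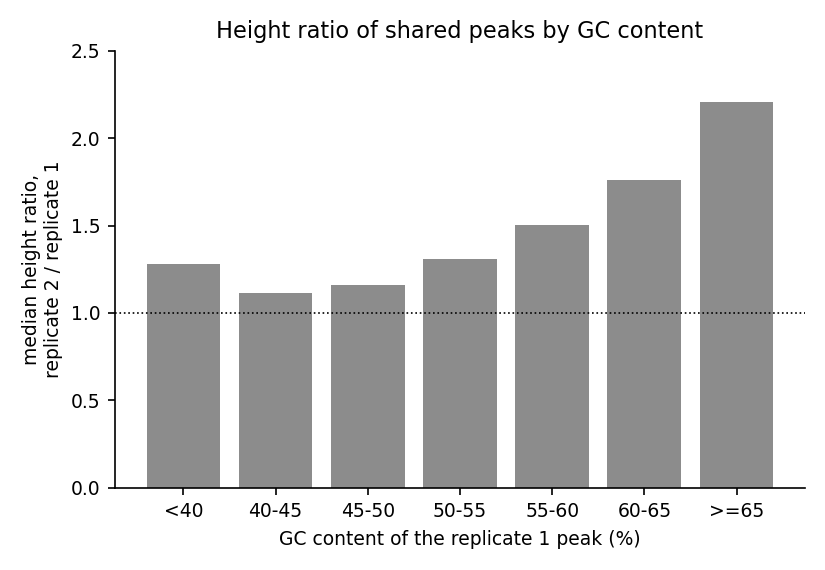
Median ratio of height in replicate 2 to height in replicate 1 for shared peaks, by GC content of the replicate 1 peak, with a dotted line at a ratio of 1. The ratio is lowest at 40 to 45% GC, at 1.11, and highest at 65% and over, at 2.21.

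The single X chromosome of these males held fewer and lower peaks than the autosomes. It had 31.5 and 22.6 peaks per Mb against 73.4 and 57.4 on autosomes, and its median peak height was 0.540 and 0.592 of theirs. The Y chromosome held 109 and 58 peaks.

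The authors' stricter list kept 121537 and 95013 peaks. Peaks holding a position with an FDR of at most 0.001 in the deposited per-position values numbered 124892 and 97149, and those at 0.01 numbered 152584 and 117997.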

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

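The gene lists on the stricter peak list or matched on GC content of the promoter, and the motifs in promoter footprints only, were tests chosen after the results were seen. Where values moved, the cause was not tested unless the setting itself gives it.

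With 50% reciprocal overlap, a narrower definition, 53.6% and 68.7% of replicate 1 and replicate 2 peaks were shared (62.3% and 80.5% in the report), Pearson's r was 0.887, Spearman's rho 0.869 and the median height ratio 1.52. The top 50000 peaks of each library gave 81.6% and 82.1%, equal numbers of the highest peaks 73.8% and 74.6%, and the stricter list 67.1% and 86.5%. The promoter share (22.4%) was 15.6% within 500 bp and 31.5% within 2500 bp, as the window's size sets it. For start sites of protein-coding genes only, whose windows cover 2.03% of the known bases, it was 18.7%. Footprints shared by 1 bp came to 41.7% and 67.1%, and in shared peaks to 36.8% and 49.0%, where the ratio of promoter to distal footprints per kb was 1.09 (1.13 in all peaks). The median height of X peaks relative to autosomes was 0.621 on the stricter list (0.566).

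Lists called high by nearby peaks fell from 4 to 2 with no matching and to 2 with matching on GC content. Motifs called less frequent numbered 8 with 0 bp added, 0 with control windows matched on GC content and 1 in promoter footprints only (4 in the report), and 4 to 7 with 1 replicate left out. AP1 sites, not called in the report (mean of 0.03 on the log2 scale), stood at -0.67 with 0 bp added. MEF2 sites, not called either, stood at -0.29 without replicate 1 and at 0.30 without replicate 2.

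By promoter height the granule neuron list was called high without replicate 2 (99.9). The counts of 3 high and 14 low lists by promoter height and of 16 more frequent motifs stayed within 1.5-fold under the alternatives run. With both replicates kept, the alternatives moved the main results, such as overlap and counts of calls, in 25 cases and left them the same in 33. For single lists, motifs, classes and promoters, each item was counted once per alternative. Of these cases, 501 had the same call, had no call in either setting or moved by less than the spread between replicates. A further 28 calls were lost, 10 were gained, 21 values moved and 1 mean changed sign (AP1). With 1 replicate left out, 144 stayed the same, 9 were gained and 1 mean changed sign (MEF2). That step could not lose a call, because a call needed both animals. Nor could it move a class share, as each of 2 values lies within 1 SD of their mean. The stricter part of the footprints by score was not run, because the score is constant. Depth sets the counting error of each peak, and the first quartile of peak height was 64 events in replicate 1 and 57 in replicate 2.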

Other observations

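Several motifs were more frequent in tall distal peaks than in low ones. Matches were counted over the whole peak, with no matching on width or GC content, and a wider peak has more places for a match. In the tallest 10% of distal peaks, 21.9% in replicate 1 and 14.05% in replicate 2 held the NEUROD1 and ATOH1 E-box, against 6.88% and 6.8003% in the lower part of distal peaks up to the median height. The ZIC box, bound by zinc finger proteins of the granule lineage, lay in 20.05% and 19.4% against 10.97% and 11.9%, and CTCF sites in 5.54% and 15.9% against 1.95% and 2.28%. TFAP2 sites (12.4% and 11.9% against 6.87% and 7.35%) and OLIG sites (4.70% and 2.38% against 2.02% and 1.72%) went the same way, and NFI sites the other way (0.449% and 0.351% against 0.620% and 0.665%). SP and KLF boxes lay in 11.1% and 12.4% of promoter peaks and in 0.936% and 1.28% of distal peaks, while the E-box lay in 3.97% and 3.05% of promoter peaks and in 10.2% and 9.21% of distal ones.

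The most peaks in or within 10 kb of a single gene lay at Gm20388 (806 and 718) and Fgfr2 (414 and 309), which are annotated as 4435 and 2961 kb long. Per 10 kb Gm20388 held 1.81 and 1.61 peaks and Fgfr2 held 1.39 and 1.04, against 3.64 and 3.17 at Rbfox3. Rbfox3, which encodes the neuronal nuclear antigen NeuN, had 161 and 140 peaks, Camta1 had 162 and 148, and Nav2, a neuron navigator gene, had 131 and 123. These genes were chosen after their values were seen. Promoter peaks of 100 to 200 events held a footprint in 65.01% and 61.7% of cases, against 89.0% and 91.0% of distal peaks of the same size.

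The design has 1 group, so no biological explanation was tested as a group difference. The 3 tests of height against GC content, the test of relative depth the test on promoters of other cell types and the comparison of the E-box with other motifs were chosen after the results were seen. Digestion and fragment size were not tested here, since the files hold no reads.

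Peak height in replicate 2 over replicate 1 rose with GC content. A single scaling factor between libraries was argued against, since the highest median ratio over the GC classes was 1.99 times the lowest. Promoters as a class were argued against as the whole cause, since within introns alone peaks of 60% GC and over had a ratio 1.63 times that of peaks below 50%. GC-dependent recovery of DNA fragments that differs between the libraries remains a candidate explanation, as the same quotient was above 1 in each of 8 strata of height and class, from 1.41 to 2.96. These strata divide the same peak pairs and are not independent of each other. Matched on GC content and height, distal peaks with CTCF (1.41) and MEF2 (-0.63) sites still differed in log2 ratio from other distal peaks. GC content need not account for all differences in height.

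Many low peaks were found in 1 library only. Lower depth of replicate 1 as a whole is argued against for the peaks of replicate 2 alone. By the ratio of the steps, replicate 1 was 1.98 times as deep. Replicate 1 can still hold fewer events at single peaks, as at shared peaks of 65% GC and over, where the median height ratio was 2.21. GC-dependent recovery may contribute, though another cause linked to GC content would give the same differences. Among peaks of 50 to 100 events, the share found in the other library at 60% GC and over was set against that below 50%. It differed by 29.6 percentage points for replicate 1 (60.2% against 30.6%) and by -16.4 for replicate 2 (63.1% against 79.6%). The calling threshold stays open for both: 6.97% of the peaks of replicate 1 alone (2.56% by chance) and 32.7% of those of replicate 2 alone (3.61%) met positions listed in the other library, but only positions past the threshold of the peak list are listed, so the low share set in advance as counting against it could not show how many regions fell just short. Depth stays open for replicate 1 alone, as 18.2% of its unpaired peaks would reach the first quartile of replicate 2 peaks, 57 events, between the bounds set in advance.

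Granule neuron promoters stood lower in replicate 2 over replicate 1 than other promoters. GC content and height of the promoter peaks are argued against, since the mean log2 ratio of 0.28 lay at percentile 0 of lists matched on both (median 0.88), and clock and imprinted genes also lay low, at percentiles 1.07 and 0.47. Promoters of other cell types, 49 of 6 lists pooled (Purkinje, interneuron, astrocyte, oligodendrocyte, precursor and vascular), lay at percentile 17.1 of matched lists. Singly, the precursor and vascular lists lay at 61.5 and 64.5, and the others from 13.6 (interneuron) to 34.35 (Purkinje). These promoters cannot decide on a lower share of granule neurons in replicate 2, since the cells behind each promoter peak are not known. Distal peaks with the E-box leave it open, as their matched log2 ratio differed by -0.50 from that of other distal peaks. However, peaks with OLIG (-0.50) and RORA (-0.55) sites were as low, while those with the ZIC box differed by only -0.09. NFI sites (0.32) were listed for granule neurons and glia, so their rise speaks neither for nor against a lower share of granule neurons. Distal peaks with AP1 (-0.38) and MEF2 (-0.63) sites were lower too and those with CTCF sites higher (1.41), so the shift was not limited to the E-box.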
